A study of Mus musculus with 67 samples.

How the data were processed

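RNA was measured in mouse microglia, the resident immune cells of the brain, from animals with a floxed Orai1 gene (WT) and from animals that also carried a tamoxifen-inducible Cre driven from the Cx3cr1 locus (KO). Orai1 is the pore subunit of the calcium channel that opens when the stores of the endoplasmic reticulum are emptied. One table held 34 libraries of primary microglia grown from the hippocampus of newborn mice. Per the labels' protocols, these cultures received 1 µM hydroxytamoxifen and, for 6 h, vehicle, LPS at 10 ng/ml, or thapsigargin at 0.2 µM with PDBu at 50 nM, and their libraries were made from 100 ng of RNA with a NEBNext kit. Thapsigargin (Tg) empties the calcium stores and PDBu is a phorbol ester that activates protein kinase C, while LPS is a bacterial cell wall component that triggers inflammatory signalling. The other table held, per its labels, 33 libraries of microglia sorted by FACS from the whole brain of mice aged 10 to 12 weeks, 30 to 35 days after tamoxifen. These mice had received vehicle or LPS at 1 mg/kg, and their libraries were made from 0.97 ng of RNA with a SMARTer total RNA kit, per the labels' protocols. Other metadata supplied with these counts describe cultured primary microglia instead, and the labels were followed. The 2 tables therefore differ in age, tissue, preparation and kit, and no model of single rows was fitted across them. Only overlaps, medians and correlations over rows were compared between the tables.

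The authors deposited whole-number counts per row, without normalization. Trim Galore 0.6.7, STAR 2.7.10a, Salmon 1.10.1 and the genome build GRCm38 are named in the submitters' processing notes, which give neither their order nor the counting settings. Both tables held 45707 rows, of which 28306 in the culture table and 32089 in the sorted table had a count in any library. The tables pair no row with a gene name or identifier, so rows are given by their number from the top, and no name was inferred from that place. The 2 tables appeared to list their rows in the same order. Across the 26168 rows with counts in both, the Spearman correlation of mean log2 CPM was 0.848, against 0.328 to 0.347 when one table was moved by 1 to 3 rows. Because of the missing names, the targeted gene could not be looked up to check the genotype labels, and the gene lists and cell type markers fixed for this work were not tested. Reads shared between near-identical or overlapping genes could not be assessed either.

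Total counts per library ran from 7868694 to 16070721 in culture, with a median of 10117679.5, and from 4989974 to 7596706 in sorted cells, with a median of 6536405. Rows with too few counts were removed with filterByExpr of edgeR 4.0.16, with a minimum count of 10 and a minimum total of 15. This left 15979 rows in culture and 15344 in sorted cells, which held 99.93% and 99.84% of the counts. Counts were scaled by TMM and tested with the quasi-likelihood F test of edgeR in R 4.3.3. All libraries of a table entered 1 model with a mean for each group of genotype, sex and treatment, and the sexes were weighted equally. A row was called when its Benjamini-Hochberg adjusted p was under 0.05. Standard errors were derived from the fold change and its F statistic, and all tests were two-sided. CPM values are means over libraries with their SD, and log2 CPM used a prior count of 2. SE and SD values cover the spread between libraries as well as counting error. The reads carry no molecular identifiers.

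The script was tested on simulated counts in which 200 rows were changed. For KO against WT in vehicle cultures, 70% of 2-fold and 97% of 4-fold changes were recovered with 8 false calls among 15406 rows. For the same comparison in sorted cells, 53% and 85% (53 and 85 rows) were recovered, with 15 false calls among 14962 rows. The changed rows were drawn from those with a mean log2 CPM of at least 1, so recovery at lower levels was not tested. The simulated spread followed its trend over mean counts alone, without differences between single rows. No pair of libraries within a group agreed within sampling noise: chi-square per degree of freedom was at least 13.7 in 32 culture pairs and at least 12.9 in 39 sorted pairs. The labels call the sorted libraries separate samples without stating which mouse each came from.

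The rule for naming genes asked for gene symbols. It was applied to row numbers instead, with at most 2 rows that rose and 2 that fell in a comparison, taken by the size of the fold change among called rows with a mean log2 CPM of at least 1 and the same direction in both sexes. Groups, tests, the naming rule and most alternatives were fixed before the data were examined. Where a group had 0 to 3 counts in total, CPM values are given without a fold change, apart from a fitted difference of row 19273 in the closing part.

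Library names in the culture table carry a number, and libraries of 1 genotype and sex with the same number received different treatments. The deviations from the group means correlated with a median of 0.22 over 30 pairs with the same number, from 0.0824 to 0.491, and 29 of them exceeded 0.1. Pairs with different numbers had a median of -0.102. The number was therefore read as a culture split across treatments, with the 1 pair below 0.1 as an exception. In order of number, the cultures ran in blocks of a single genotype. These were WT 3 and 4, KO 6 to 8, WT 9 to 14 and KO 15 to 18. The sorted libraries share only replicate numbers in their titles. Their library numbers fall into a first run, 3299 to 3315, a second run, 3376 to 3402, and a run from 68 to 73 that held the 6 h mice and no others.

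The alternatives were DESeq2 1.42.0, RLE size factors in place of TMM, no filter on low counts, a model of the compared groups alone, voom with quality weights in limma 3.58.1, a replicate block, a term for the run of library numbers, and the omission of each library in turn. Fits within each run of library numbers, and fits without WT female culture 3, were added after the data were seen. Other groupings of the samples were tested by permuting the compared label within the other factors, with 100 splits where more than 100 exist. An initial 25 splits per comparison were replaced by 100 after 2 separate draws had given 1 and 3 splits as large as the real one for the genotype comparison at 24 h in sorted cells.

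Rows specific to a sex were those with at least 20 CPM in every sorted library of that sex and more than 5 times the highest library of the other. The ratio was lowered from 10 to 5 after the data were seen, since no female-specific row passed at 10. Sex labels of sorted libraries were then checked on levels relative to each sex, after a first check on raw CPM had set 2 libraries against their label. The rows had been chosen by those labels in the same libraries, so this is not a separate check. The LPS score of a sorted library was its mean log2 CPM difference from the vehicle libraries over 580 rows called in WT cultures with LPS at a log2 fold change above 2.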

Results

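The series compared RNA levels of KO and WT microglia at rest and after stimulation, in both sexes, in culture and in the animal. The KO animals carried the Cre driven from the Cx3cr1 locus and the WT animals did not. An effect of Orai1 loss therefore cannot be told apart from an effect of the Cre. The culture table comprised 34 libraries in 12 groups of genotype, sex and treatment. Each group had 3 libraries, except KO females with LPS and KO females with Tg+PDBu, which had 2. The sorted table comprised 33 libraries in 10 groups of 3 or 4. Vehicle and 24 h LPS were sampled in both sexes, whereas 6 h LPS was sampled in males, with 3 WT and 3 KO mice. Depth ranged from 7868694 to 16070721 counts per library in culture and from 4989974 to 7596706 in sorted cells. Genes are referred to by row number because the tables pair no row with a name.

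Row 1 separated the genotypes as labelled. It had the lowest adjusted p in each sorted comparison of KO with WT, so in sorted cells it is no separate check of the labels. It does not show the loss of Orai1. In sorted KO cells it held 505 to 1642 counts in every one of the 16 libraries, whereas the 17 WT libraries held 0 to 2 counts each. In KO cultures it reached 10.4 ± 2.21 CPM with vehicle (SD, n = 6), and all 18 WT culture libraries had 0 counts. Its level in KO cultures depended on treatment: it was 3.82 ± 1.09 CPM in females (n = 2) and 3.17 ± 0.701 CPM in males (n = 3) with LPS, and 0.132 ± 0.105 CPM with Tg+PDBu (n = 5). The last level is too low to look at the labels of those libraries.

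Store depletion with PDBu changed about as many rows in WT as in KO cultures. In WT cultures 3849 rows rose and 4325 fell. Row 759 rose by 7.95 ± 0.90 on the log2 scale (SE, adjusted p = 5.38e-08), from 0.12 to 29.3 CPM (n = 6 each), and row 59 rose by 7.61 ± 0.50 (adjusted p = 2.67e-12). Row 7999 changed by -5.73 ± 0.64 (adjusted p = 3.57e-08) and row 15292 by -5.52 ± 0.34 (adjusted p = 9.32e-13), the latter from 313 to 6.79 CPM. In KO cultures 2859 rows rose and 4929 fell. Row 16627 rose by 7.01 ± 0.60, from 1.58 to 180 CPM (n = 6 and 5), and row 7267 by 6.81 ± 0.39. Row 15292 fell here too, by -5.22 ± 0.39, as did row 1, by -6.34 ± 0.48. The genotypes shared 2292 of the rows that rose and 3189 of those that fell, where independent lists of these sizes would share 689 and 1330. With RLE size factors, which moved the fold changes in KO cultures by 0.13 on the log2 scale, the KO counts became 3534 higher and 3857 lower. In fits of the compared groups alone the balance of directions turned, to 3960 higher and 3690 lower in WT and 4197 and 3950 in KO. In WT it also turned with RLE (4091 and 4069) and without WT male vehicle replicate 1 (3903 and 3898).

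The response to Tg+PDBu itself differed between genotypes in 1991 rows, 772 with a higher and 1219 with a lower response in KO. Of these, 848 rose in WT and had a lower response in KO, and 524 fell in WT and had a higher one. Divided by where they were called, the same 1991 rows comprised 663 called in WT alone and 427 in KO alone, 569 called in both with the smaller change in KO, 185 in both with the larger change in KO, 140 in opposite directions and 7 in neither. Row 759, which rose to 29.3 CPM in WT cultures, stood at 0.624 ± 1.25 CPM in KO cultures with Tg+PDBu (SD, n = 5). Row 8635 had a response higher in KO by 3.32 ± 0.35 (adjusted p = 6.84e-07), and row 11919 a response of -5.48 ± 0.59 relative to WT (adjusted p = 9.53e-07). The balance of directions depended on scaling, with 1070 higher and 876 lower under RLE and 1369 and 1193 with DESeq2, and the total rose to 2995 with voom and quality weights.

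LPS raised 3489 and lowered 4186 rows in WT cultures, against 1388 and 2248 in KO cultures. The same 2 rows led the rise in both genotypes. Row 693 reached 939 ± 541 CPM in WT (SD, n = 6) from 0.517 CPM with vehicle, and 166 ± 107 CPM in KO (n = 5), where the 6 vehicle libraries held 3 counts in total. Its fitted log2 change in WT was 13.04 ± 0.94 (SE, adjusted p = 1.57e-10). This value averages the log2 changes of the sexes and exceeds the log2 ratio of the mean CPM values. Row 6096 reached 6170 ± 3150 CPM in WT and 657 ± 388 CPM in KO, with log2 changes of 11.99 ± 0.77 and 11.41 ± 0.83. Row 17577 changed by -5.97 ± 0.34 and row 13438 by -5.13 ± 0.23 in WT, and row 11032 by -3.97 ± 0.48 and row 20036 by -3.72 ± 0.42 in KO. The balance of directions depended on scaling. With RLE the WT counts became 4082 higher and 3604 lower, and the KO counts, whose fold changes it moved by 0.11, became 1916 and 1462. DESeq2 gave 4226 higher and 3720 lower in WT and 2091 and 1730 in KO. In KO the balance turned also in a fit of the compared groups alone (1852 and 1584) and without KO female LPS replicate 2 (1381 and 1320).

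The LPS response differed between genotypes in 2527 rows of the culture table, 944 with a higher and 1583 with a lower response in KO. Among them, 1481 rose in WT and had a lower response in KO, and 913 fell in WT and had a higher response in KO. Divided by where they were called, 1422 of the same 2527 rows were called in WT cultures and not in KO cultures, and 949 were called in both with the smaller change in KO. Of the rest, 77 were called in KO alone, 8 in both with the larger change in KO, 23 in opposite directions and 48 in neither. The balance of directions turned in a similar way on omitting different WT LPS libraries. It was 1531 higher and 838 lower without WT female LPS replicate 1, and 1415 and 716 without WT female replicate 2. Without WT male replicate 1 it was 1431 and 759, and without WT male replicate 3 it was 1443 and 743. With all libraries, lower rows stayed in excess under RLE (1038 higher and 1528 lower) and DESeq2 (1321 and 1851). Row 21028 had a response higher in KO by 7.72 ± 2.13 (SE, adjusted p = 0.0164), with an adjusted p of 0.0939 under voom. Row 6073 had a response of -5.44 ± 0.93 relative to WT (adjusted p = 0.000322).

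KO and WT cultures differed without any stimulus. With vehicle, 4807 rows were higher and 3784 lower in KO, together 53.8% of the rows tested. The excess of higher rows depended on the method, with 4539 higher and 4427 lower under RLE, 4715 and 4638 with DESeq2, and 4527 and 4555 in a fit of the compared groups alone. The changes upward were larger: 3546 rows were more than 2-fold higher and 646 more than 2-fold lower. Row 15267 was higher by 4.48 ± 0.54 (SE, adjusted p = 3.53e-07), at 38 ± 13.3 against 1.65 ± 1.49 CPM (SD, n = 6 each). Row 1805 was higher by 5.77 ± 1.3, with an adjusted p of 0.117 when the culture was a block and 0.0905 with voom. Row 16627 was lower by -3.65 ± 0.55 and row 1847 by -3.28 ± 0.50. With Tg+PDBu 4514 rows were higher and 4562 lower in KO, a balance that turned with RLE (4689 and 4295), and with LPS 5312 and 4809, which turned without KO female LPS replicate 1 (4884 and 5082) or 2 (4406 and 4574). In all 3 treatments 3005 rows were higher and 2142 lower, and 726 rows were called in opposite directions in some pair of treatments. The largest fitted falls under LPS were those of rows 19565 and 19566, with 0 counts in both KO female LPS libraries. Both are male-specific rows, defined below, and were detected in males but hardly in females outside WT female culture 3. In WT female LPS replicate 3, of that culture, the male-specific rows together stood at 0.417 of the male level. The fitted falls became smaller without this library, so they do not show an effect of genotype alone. Their calls ended when the culture was a block (adjusted p = 0.103 and 0.0773), without WT female LPS replicate 3 (0.287 and 0.203), without KO female LPS replicate 1 (0.0954 and 0.0792), without KO female LPS replicate 2 (0.10 and 0.0832), without a filter (0.0816 and 0.0661) and with voom (0.215 and 0.208). Without any library of WT female culture 3, both were called (0.0366 and 0.0356).

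**Figure D1:**
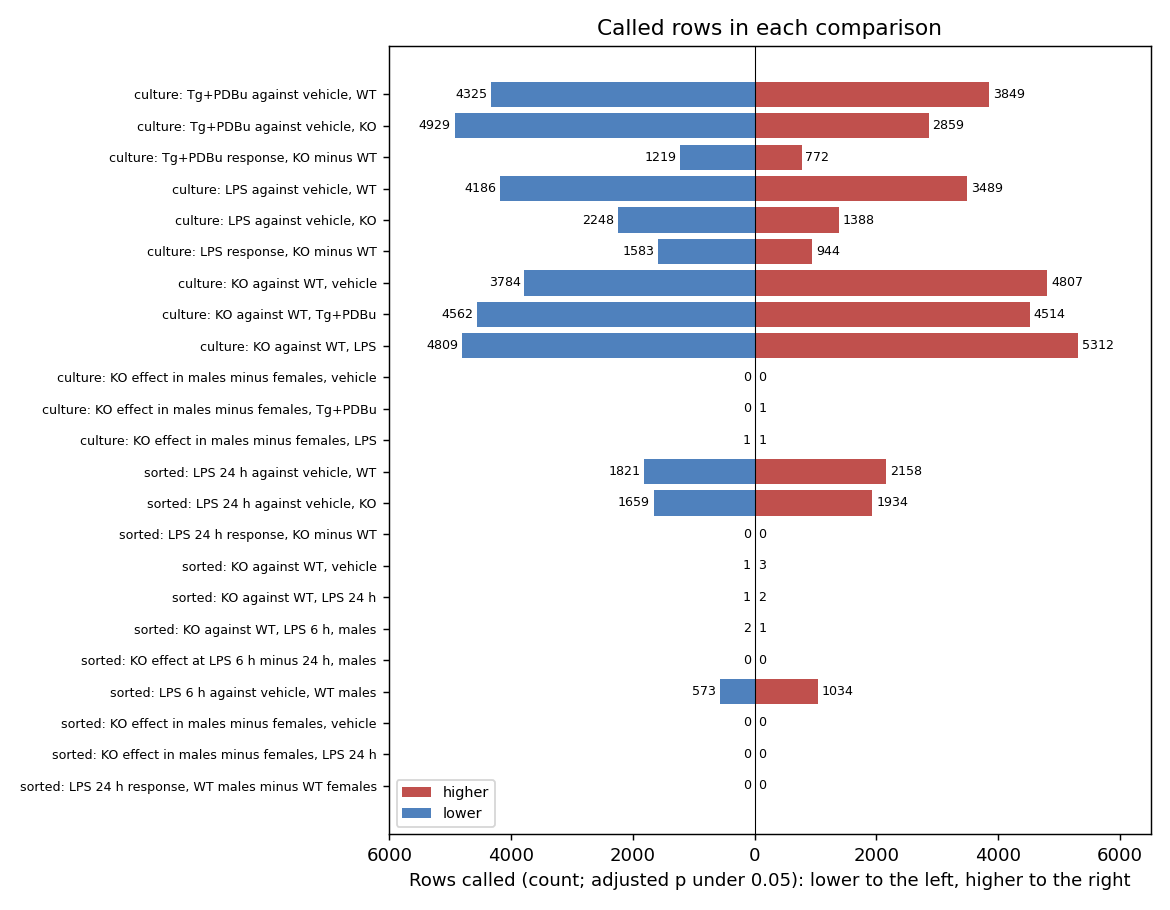
Number of rows called in each comparison by edgeR, with rows that were higher drawn to the right in red and rows that were lower to the left in blue. KO against WT gave 4807 higher and 3784 lower rows in vehicle cultures, and 3 higher and 1 lower in sorted vehicle cells.

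The genotype effect in culture was compared between the sexes in a direct test. With vehicle, edgeR called 0 rows for males minus females, with 820 rows at an unadjusted p under 0.05 where chance gives 799. DESeq2 called 27 and voom 6. Leaving out KO male replicate 3 gave 2 calls, and leaving out KO female replicate 3 gave 1. Taken for each sex from the same model, the fold changes of females and males correlated across rows with a Spearman coefficient of 0.802, although rows are not independent replicates. With Tg+PDBu 1 row was called, row 19273, at no more than 4.18 CPM in any library and at 0 in both KO female libraries. This call became 0 with the culture as a block and without any library but WT male replicate 1, except that 2 rows were called without KO male replicate 3. DESeq2 called 4 rows and voom 0.

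With LPS, 2 rows differed between the sexes in their genotype effect, with 1562 rows at an unadjusted p under 0.05 where chance gives 799. Row 901 was at 61.2 ± 3.35 CPM in KO males and 28.3 ± 8.01 in WT males (SD, n = 3 each), but at 36.2 ± 1.49 in KO females (n = 2) and 46.3 ± 8.25 in WT females (n = 3), a difference of 1.46 ± 0.24 (SE, adjusted p = 0.0151). Row 5844 went the other way, by -1.86 ± 0.30 (adjusted p = 0.0151). Row 901 lost its call without KO female replicate 2 (0.0573), KO male replicate 1 or 3 (0.0553 and 0.0647) or WT female replicate 2 (0.0656), and row 5844 without KO male replicate 1 or 3 (0.0607 and 0.0647). The count was 2 here, whereas 5 rows were called with the culture as a block, 83 by DESeq2 and 0 by voom. Without KO female replicate 1 there were 23, without KO female replicate 2 there were 8, and without WT female replicates 1, 2 and 3 there were 12, 1 and 4. Without WT male replicates 1 and 3 there were 11 and 4, and without KO male replicate 1 or 3 there were 0.

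Rows specific to a sex were sought in the sorted cells and then read in the cultures. In sorted cells 4 rows were detected in every male library and hardly in females. One of them, row 19565, averaged 109 CPM in males and 0.0902 CPM in females. Row 28290 was specific to females, at 2090 against 14.8 CPM. The sex rows went against the label in 0 of the 33 sorted libraries. They had been chosen by these labels in the same libraries, so this count is no separate check of the labels. In culture, the male-specific rows of WT female culture 3 stood at 0.417 to 0.545 of the level of male cultures in its 3 libraries, and its female-specific row at 0.254 to 0.60 of the level of female cultures. In the 13 other female culture libraries the male-specific rows stood at 0 to 0.0474 and the female-specific row at 0.642 to 1.56. These libraries are called WT female culture 3, as labelled, throughout.

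**Figure D2:**
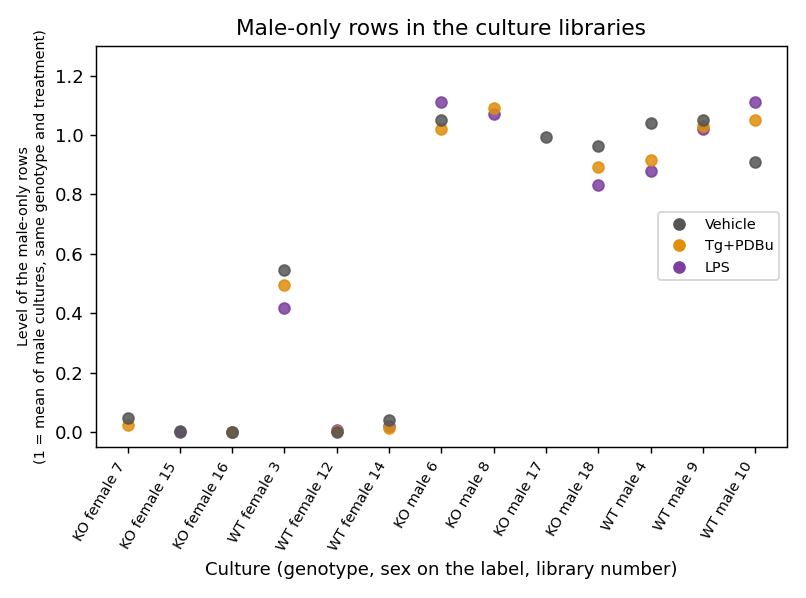
Level of the 4 male-specific rows in each culture library, as a share of male cultures of the same genotype and treatment, by culture and colored by treatment. The 3 libraries of WT female culture 3 lie at 0.417 to 0.545, and the other female libraries at 0.0474 or below.

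In sorted cells, LPS for 24 h raised 2158 and lowered 1821 rows in WT mice, and raised 1934 and lowered 1659 in KO mice. Row 11765 rose in both genotypes, to 87.7 ± 62.2 CPM in WT (SD, n = 8) and 66.3 ± 30.7 CPM in KO (n = 7), where the 6 vehicle libraries of each genotype held 2 counts in total. Its adjusted p under voom was 0.0618 in WT and 0.0816 in KO. Row 5524 rose to 46.7 ± 43.1 CPM in WT from 3 counts in 6 vehicle libraries. Row 6411 fell by -4.55 ± 0.51 (SE, adjusted p = 3.12e-07) and row 2671 by -4.40 ± 0.50 in WT, and row 375 by -4.47 ± 0.85 and row 22925 by -4.27 ± 0.62 in KO. Row 375 was not called within the first run of library numbers (adjusted p = 0.138) and row 22925 not within the second (0.095). The genotypes shared 1529 rows that rose and 1178 that fell, against 272 and 197 for independent lists, and no row was called in opposite directions. Within the first run of library numbers 2384 rows were called in WT and 2238 in KO, and within the second run 1943 and 1215.

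The 24 h response to LPS was not detectably different between genotypes in sorted cells. With edgeR 0 rows were called for the KO minus the WT response, with 530 rows at an unadjusted p under 0.05 where chance gives 767. DESeq2 called 10 rows and voom 1. The lowest adjusted p was that of row 9459, at -0.75 ± 0.13 (adjusted p = 0.0705), and it fell to 0.0301 with a term for the run of library numbers. Leaving out KO male LPS replicate 4 gave 2 calls, and leaving out KO male vehicle replicate 2 or WT female LPS replicate 2 gave 1 each.

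Few rows separated KO from WT sorted cells at any condition. Row 1 was at 225 ± 20.2 CPM in KO vehicle mice (SD, n = 6), with 1 count in total in the 6 WT libraries, and at 167 ± 23.2 CPM in KO mice 24 h after LPS (n = 7). Row 43535 was higher in KO by 2.61 ± 0.32 with vehicle (SE, adjusted p = 8.79e-05) and by 3.22 ± 0.30 at 24 h (adjusted p = 2.64e-07). Row 14617 was lower in KO by -1.26 ± 0.18 with vehicle (adjusted p = 0.000612) and by -1.49 ± 0.16 at 24 h (adjusted p = 5.44e-06). These were all the rows called at 24 h, and with vehicle a further row, 9459, chosen after its value was seen, was higher by 0.57 ± 0.10 (adjusted p = 0.0115). Row 9459 lost this call without a filter (0.11), in a fit of the compared groups alone (0.664) and within both runs of library numbers (0.219 and 0.191). It also lost it without KO female replicate 1 (0.073), KO male replicate 1 or 3 (0.0633 and 0.0728), WT female replicate 1 (0.0645) or WT male replicate 2 (0.0609). DESeq2 called 21 rows with vehicle and 15 at 24 h. Within the 2 runs of library numbers row 14617 kept its direction without a call, at -1.43 and -1.35 with vehicle (adjusted p = 0.201 and 0.071) and at -1.58 and -1.39 at 24 h (0.0571 and 0.185). With vehicle it also lost its call in a fit of the compared groups alone (0.09). Row 43535 lost its call within both runs with vehicle (0.458 and 0.101) and within the second at 24 h (0.185). Within the runs, 4 and 21 rows were called with vehicle.

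**Figure D3:**
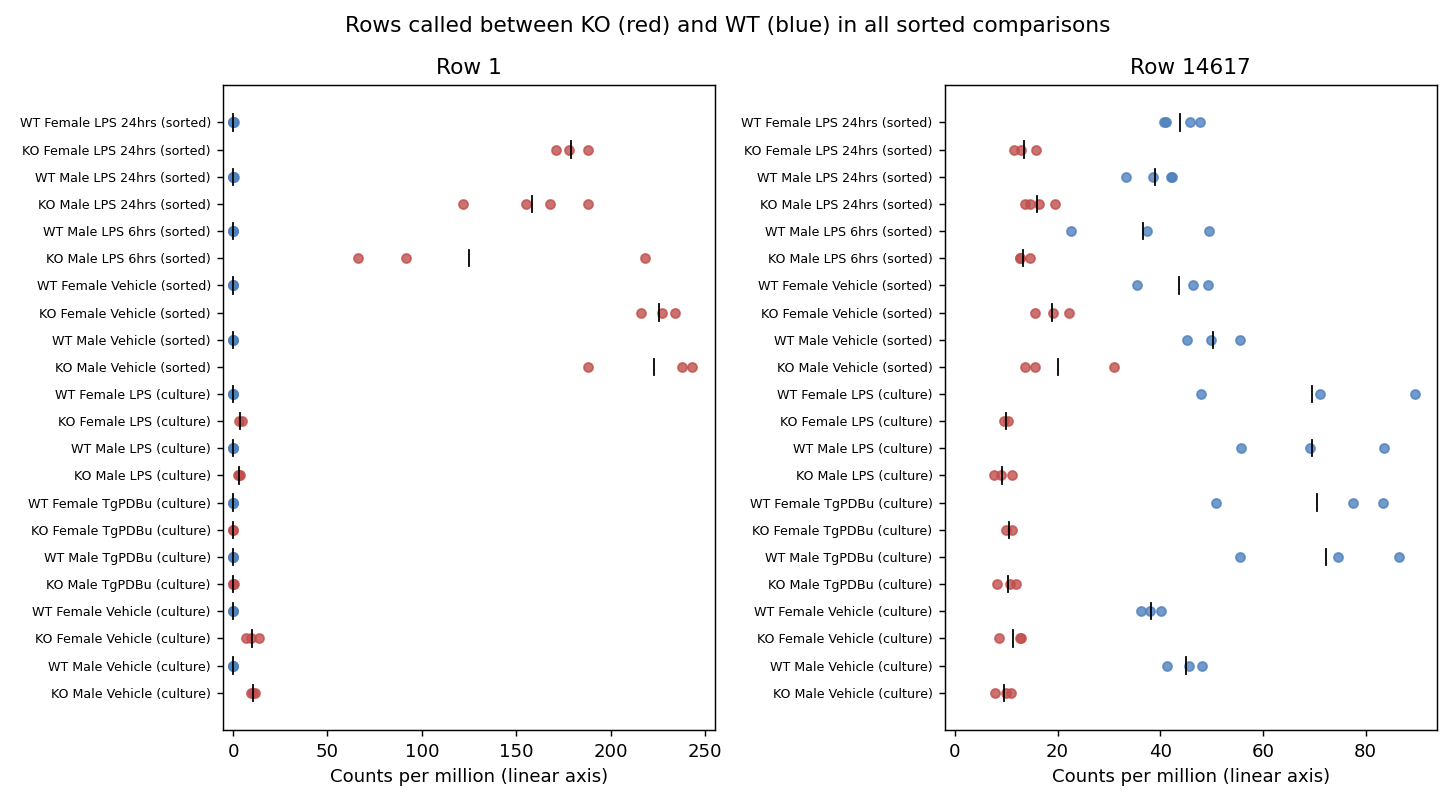
CPM of rows 1 and 14617 in each library of both tables, by group, with KO in red, WT in blue and a black line for the mean of each group. Row 1 lies at 66 to 243 CPM in sorted KO cells and near 0 in WT cells, and row 14617 lies lower in KO than in WT in each matched pair of groups.

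At 6 h after LPS, KO males differed from WT males in 3 rows. Row 1 held 505 to 1523 counts in the 3 KO mice and 0 counts in the 3 WT mice. Row 14617 was lower by -1.46 ± 0.25 (SE, adjusted p = 0.0209) and row 3519 by -1.56 ± 0.25 (adjusted p = 0.00669), at 13.2 ± 1.41 against 38.7 ± 12.9 CPM (SD, n = 3 each). Row 43535 was higher by 2.25 ± 0.45 without passing the threshold (adjusted p = 0.0922). Row 14617 lost its call on leaving out any of the 3 KO mice (adjusted p = 0.0549, 0.189 and 0.157 without replicates 1, 2 and 3), WT replicate 1 (0.0794) or WT replicate 3 (0.102). Row 3519 lost it without KO replicate 2 or 3 (0.17 and 0.06) or WT replicate 3 (0.0644). The count was 5 without KO replicate 1 and 1 without KO replicate 2 or 3, and it was 0 in a fit of the 2 groups alone, 6 with voom and 11 with DESeq2.

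The genotype effect at 6 h was not detectably different from that at 24 h in males. With edgeR 0 rows were called for 6 h minus 24 h, with 765 at an unadjusted p under 0.05 where chance gives 767, while DESeq2 called 11 and voom 0. Row 3519 had the lowest adjusted p, 0.0768, at -1.83 ± 0.32. Leaving out WT 6 h replicate 2 gave 2 calls, and leaving out WT 6 h replicate 1 or KO 24 h replicate 4 gave 1.

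The 6 h mice had no vehicle mice of their own, so WT males at 6 h were set against the WT vehicle males of the other runs of library numbers. On that basis 1034 rows were higher and 573 lower, and the run and the time after LPS cannot be told apart. Row 7224 was higher by 7.37 ± 1.42 (SE, adjusted p = 0.00177), at 337 ± 313 CPM (SD, n = 3). Row 9906 was at 30 ± 24.5 CPM, with 3 counts in the 3 vehicle libraries. The count of 1607 rows became 414 and 515 without WT 6 h replicates 2 and 1, 2997 without WT 6 h replicate 3, and 780, 1046 and 1012 without WT vehicle replicates 1, 2 and 3. It was 967 without a filter, 3975 with voom and 0 in a fit of the 2 groups alone.

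**Figure D4:**
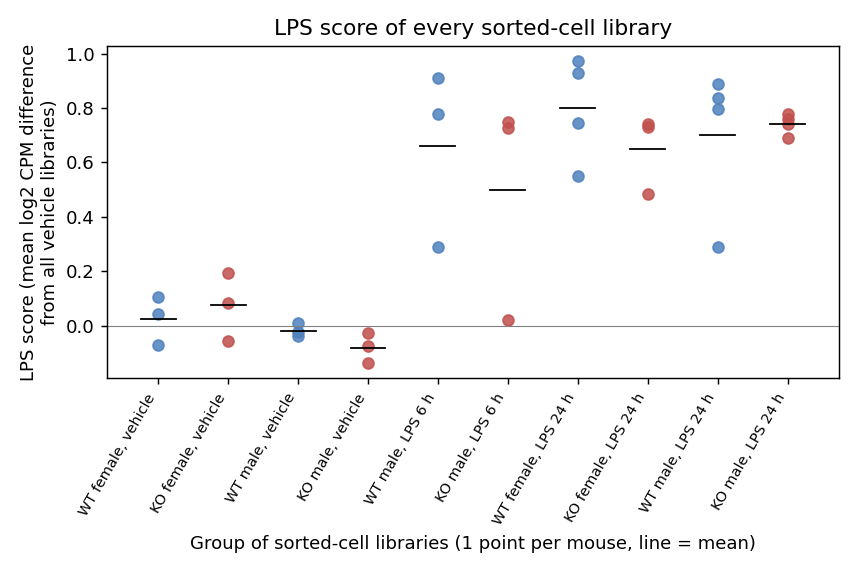
LPS score of each sorted library, the mean log2 CPM difference from the vehicle libraries over 580 rows that LPS raised more than 4-fold in WT cultures, with a point per mouse, KO in red, WT in blue and a line for each mean. The 12 vehicle libraries lie between -0.139 and 0.195, and among the 6 h libraries WT replicate 3 lies at 0.289 and KO replicate 1 at 0.019.

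Sexes were compared in sorted cells as well. The genotype effect in males minus that in females gave 0 calls with edgeR with vehicle and at 24 h, with 714 and 767 rows at an unadjusted p under 0.05 where chance gives 767. DESeq2 called 11 and 2, and voom 0 in both. Without KO male vehicle replicate 1 the vehicle count was 2. The LPS response of WT males minus that of WT females also gave 0 calls with edgeR, with 570 rows at an unadjusted p under 0.05, 7 calls by DESeq2 and 0 by voom.

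Responses in culture and in the animal overlapped in part. Of rows tested in both tables, 924 rose with LPS in WT cultures at 6 h and in sorted WT cells at 24 h, against 492 for independent lists, and 684 fell in both, against 477. Opposite directions were seen in 731 rows, against 993 for independent lists. The fold changes correlated across rows with a Spearman coefficient of 0.159. Between cultures and sorted WT males at 6 h the shared rise covered 523 rows, against 241. The genotype effect showed no such overlap across rows: its coefficient between vehicle cultures and sorted vehicle cells was -0.175, and the medians of the rows called higher and lower in KO cultures were -0.0603 and 0.029 in sorted cells, against 1.58 and -0.542 in culture.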

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

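Among the tests in this part, those of a male culture under a female label, of reads spilled over from male libraries and of the depth of the 6 h libraries, with the look at row 1 in the 6 h mice, were chosen only after the result was seen, as was the reading of a mixture by single libraries. The test of a second cell population was first run on rows tested in both tables and then extended to all called rows, because the first form left out 1312 of the 4807 rows higher in KO.

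KO and WT vehicle cultures differed in 8591 of 15979 rows, whereas sorted vehicle cells of the same genotypes differed in 4. The choice of TMM over RLE does not account for this, since RLE size factors gave 8966 calls and moved the fold changes by -0.05. Both methods assume that most rows are unchanged, so a scaling error common to both could not be excluded. An effect of the genotype that adult sorted microglia share does not account for it either, among the rows tested in both tables. The median sorted KO effect of the 3495 higher in KO cultures lay -0.0893 on the log2 scale from that of the 3651 lower in KO cultures. A shared effect predicted a positive difference. A candidate explanation is RNA of a second cell population whose share differs between KO and WT cultures. It predicted that rows higher in KO cultures would lie far lower in sorted cells relative to their culture level, by under -1. In the extended form the value was -0.395 against the rows lower in KO and -0.802 against rows not called. In the first form the difference was smaller: the medians of sorted minus culture log2 CPM were -0.584 for rows higher and -0.38 for rows lower in KO. Below the count filter in sorted cells fell 27.3% of the rows higher in KO, 3.51% of those lower in KO and 15.6% of the others. The bound of -0.5 set for excluding a second population was passed, but the tables differ in age, preparation and kit and the comparison group itself lay -0.407 from uncalled rows, a reason added after the value was seen. A second population therefore cannot be told apart from an effect of the genotype that is limited to cultured newborn cells, which was not tested. Such an effect could come from Orai1 loss or from the Cre that only KO animals carried. The culture numbers also ran in blocks of a single genotype. A difference between such blocks cannot be told apart from genotype and was not tested.

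WT female culture 3 carried male-specific rows in all 3 of its libraries. A male culture under a female label would show them at the level of male cultures, and their mean level was 0.486 of it. Spillover of reads from male libraries would give a small share, and the lowest of the 3 libraries stood at 0.417. A mixture of male and female cells in this culture predicted that the male and female shares add up to between 0.8 and 1.2, and the sum of their means was 0.865, but the sums were 0.671 with LPS, 0.78 with Tg+PDBu and 1.14 with vehicle, and the single female-specific row ran from 0.642 to 1.56 in other female libraries, so that a mixture stays open. No biological explanation was tested, and counts without this culture stayed within 1.5 times for every comparison except those between the sexes with Tg+PDBu (0) and LPS (6).

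At 6 h after LPS, WT male replicate 3 and KO male replicate 1 had LPS scores of 0.289 and 0.019, while the other 4 mice lay between 0.725 and 0.912. An exchange with a vehicle mouse of the series is argued against, since no vehicle library scored above 0.195. The run of the 6 h mice held no vehicle mice, so an exchange with one outside the series could not be seen. Low depth is also argued against, since the lower total of these libraries was 0.969 of the median of the others. Row 1, which stood at 91.4 and 66 CPM in the other 6 h KO mice, stood at 218 CPM in KO replicate 1, within the 188 to 243 CPM of KO vehicle males. A failed injection or a slower response could give this and was not tested, and no biological explanation was tested.

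Dixon's test on 63 groups of values pointed to 7 libraries or values that lay apart from their group, where chance gives about 1 in 20. At 24 h after LPS, row 22925 stood at 1.04 log2 CPM in KO male replicate 4 and at -1.7 in the others. In WT females, row 7224 stood at 2.49 in replicate 3, against 4.56 to 4.75 in the others, and row 5394 at 5.57 in replicate 4, against 0.255 to 0.549. The total of WT female replicate 3, at 6382296 counts, lay above the narrow range of its group. In WT males, row 43535 stood at -0.412 in replicate 1, against 1.03 to 1.3, row 9906 at 1.72 in replicate 2, against 6.1 to 6.2, and the LPS score at 0.289 in replicate 2, against 0.797 to 0.887.

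In culture, 3 rows had a genotype effect that differed between the sexes by the test of the difference itself. Row 19273 with Tg+PDBu had a fitted difference of 10.71, which is no bound because the KO female libraries held 0 counts. With LPS, row 901 had a difference of 1.46 and row 5844 one of -1.86, males minus females.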

How the results depend on the processing

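The fits within each run of library numbers and those without WT female culture 3 were chosen only after the data were seen. RLE size factors moved no total of calls by over 1.5 times, but the rows lowered by LPS in KO cultures went from 2248 to 1462. The balance of higher and lower rows turned in culture under several alternatives, with the counts given with each comparison. For KO against WT with Tg+PDBu it turned also with DESeq2 (4821 and 4456), without a filter (4437 and 3981), with the compared groups alone (4384 and 4371), with voom (4819 and 4786) and with the culture as a block (4606 and 4535). The same balance turned without KO male Tg+PDBu replicate 3 (4342 and 4307), WT female replicate 1 or 2 (4262 and 4218, 4221 and 4193) or WT male replicate 1 (4285 and 4162). Of 66 values of named rows 34 kept their side of the threshold under every alternative other than single omissions and 52 under every single omission, all with their direction. The alternatives with gene lists were not run, since the tables pair no row with a name. The cause of these changes and those below was not tested, apart from fits within a run of library numbers and fits of the compared groups alone, which use fewer samples.

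DESeq2 gave 27, 4 and 83 calls for the sex difference in genotype effect in culture (vehicle, Tg+PDBu, LPS). In sorted cells it gave 10 for the LPS response KO minus WT, 21, 15 and 11 for KO against WT (vehicle, 24 h, 6 h), 11 for 6 h minus 24 h, 11 and 2 for the sex difference in genotype effect (vehicle, 24 h) and 7 for WT males minus WT females. Without a filter the 6 h comparisons gave 5 (KO against WT) and 967 (against vehicle). Fits of the compared groups alone gave 0 for the culture sex differences with Tg+PDBu and LPS and 0 for both 6 h comparisons. Voom with quality weights gave 2995 for the Tg+PDBu response KO minus WT, 6, 0 and 0 for the culture sex differences, 1 for the sorted LPS response KO minus WT, and 6 and 3975 at 6 h.

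With the culture as a replicate block, the culture sex differences gave 0 with Tg+PDBu and 5 with LPS, and no other culture count moved by over 1.5 times. The title numbers of the sorted libraries do not pair them, with a median correlation of 0.00572 over 138 pairs, and a replicate block on them moved no count by over 1.5 times. A term for the run of library numbers gave 1 call for the sorted LPS response KO minus WT. Within the first run, 24 h LPS gave 2384 calls in WT and 2238 in KO, the response KO minus WT 2, and the sex difference with vehicle 2. Within the second run these LPS counts were 1943 and 1215, KO against WT with vehicle gave 21, and the sex differences gave 1 (vehicle), 1 (24 h) and 1 (WT response). Without WT female culture 3 the culture sex differences gave 0 with Tg+PDBu and 6 with LPS.

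Leaving out 1 library at a time gave ranges of 0 to 23, 0 to 2 and 0 to 2 calls for the culture sex differences (LPS, Tg+PDBu, vehicle), 1 to 5 for KO against WT at 6 h, 0 to 2 for 6 h minus 24 h, 0 to 2 for the sorted LPS response KO minus WT, 0 to 2 for the sorted sex difference with vehicle, and 414 to 2997 for WT males at 6 h against vehicle. The libraries behind these are named with each comparison. In the remaining comparisons no single omission moved the total by over 1.5 times. In simulated counts 53% of 2-fold changes between sorted KO and WT vehicle mice were recovered, against 70% in culture, and the shares due to depth and to spread between mice were not separated.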

Other observations

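The splits of the samples for the Tg+PDBu response in KO cultures, the LPS response in WT cultures, the LPS response KO minus WT in culture, KO against WT with Tg+PDBu, and the sex difference with vehicle in culture were planned only after a first result had been seen, as were the choice to move whole cultures between genotypes and the divisions of splits by what they kept of the real one or which mice they put together. The scores below were also chosen after the counts had been seen.

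Responses were compared in size on rows chosen without the libraries they were measured in. Rows called in 1 sex with a change over 2-fold were scored in the other sex, for a culture as treated minus its own vehicle library, in 12 tests with Benjamini-Hochberg adjustment. Rows that LPS raised in WT cultures rose by 2.35 ± 0.272 on the log2 scale in WT (SD, n = 6 cultures) and by 1.38 ± 0.218 in KO (n = 4), a difference of -0.969, and rows that it lowered fell less in KO, by a difference of 0.722. Both had an exact permutation p of 0.01, the smallest that the 100 permutations can give, and an adjusted p of 0.024. Rows chosen in KO cultures gave differences of -0.835 (exact p = 0.01, adjusted p = 0.024) and 0.60 (exact p = 0.02, adjusted p = 0.04), so the smaller response did not depend on choosing the rows in WT. Without WT female culture 3 the 4 LPS differences were -1.05, 0.78, -0.877 and 0.656, but each had an exact p of 0.0333, where 0.0167 is the smallest possible, and an adjusted p of 0.0667, which ends these calls. The culture was left out of the scores alone and stayed in the model that chose the rows.

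For Tg+PDBu the outcome depended on where the rows were chosen. Rows raised in WT cultures rose by 1.82 ± 0.115 in WT and 1.26 ± 0.0778 in KO (difference -0.562), and rows lowered in WT differed by 0.338, each with an exact permutation p of 0.01 and an adjusted p of 0.024. Rows raised in KO cultures differed by -0.0138 (exact p = 0.80, adjusted p = 0.80) and rows lowered there by -0.127 (exact p = 0.06, adjusted p = 0.103). With RLE these became 0.064 (exact p = 0.41) and -0.0454 (exact p = 0.39), so neither direction was settled. Without WT female culture 3 in the scores, the differences in rows chosen in WT were -0.568 and 0.343, each with an exact p of 0.0167 and an adjusted p of 0.0667, and the first of those chosen in KO was 0.0161. In sorted cells, none of the 4 scores of the 24 h LPS response differed past the threshold between 8 WT and 7 KO mice: the differences were -0.103, 0.0924, -0.162 and 0.0817, with exact permutation p of 0.492, 0.401, 0.216 and 0.411 and a smallest possible p of 0.00041. Sorted scores were taken from the mean of the vehicle mice of the same genotype and sex, whose error these permutations leave out. The first 2 of these differences were -0.107 and 0.0519 within the first run of library numbers and -0.107 and 0.158 within the second. For rows raised in WT, WT male replicate 2 scored 0.971, the other WT males 1.58 to 1.66 and KO males 1.41 to 1.49. In females, WT mice scored 1.53 to 2.09 and KO mice 1.22 to 1.89. Apart from WT male replicate 2, every WT male exceeded every KO male in size in all 4 scores. The scores were not tested without this mouse, so a smaller response in KO is not excluded.

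Responses to different stimuli in culture were compared between sexes so that no vehicle library was shared. Tg+PDBu in WT females and LPS in WT males raised 975 rows in common, against 463 for independent lists, and lowered 1392, against 556. In sorted cells, LPS at 24 h in WT females and at 6 h in WT males raised 535 rows in common, against 84.1, and lowered 237, against 37, with opposite directions in 9.

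Small amounts of the female-specific row were present in sorted male libraries. KO male replicate 4 at 24 h stood at 8.81% of the female level and WT male replicate 4 at 24 h at 4.38%. In addition, KO male replicate 1 at 24 h held 97 counts, and the other 17 male libraries lay at or below 0.109%.

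Other splits of the samples were refitted for each count of calls that compares groups of at least 3, with the real split counted among them. In culture, the real split gave the highest count of 100 splits for Tg+PDBu in WT (8174, next 4683), Tg+PDBu in KO (7788, next 6291), LPS in WT (7675, next 5157), LPS in KO (3636, next 2492), KO against WT with vehicle (8591, next 4994) and KO against WT with Tg+PDBu (9076, next 8881), so 1 of 100 was as large. This excludes chance at 0.05 for KO against WT with vehicle and with Tg+PDBu, where each library came from a separate culture, if cultures can be exchanged freely. Their numbers ran in blocks of a single genotype, so a difference between blocks is not excluded. For the 4 responses to treatment chance is not excluded in this way, because the splits ignored the cultures. For KO against WT with LPS, 2 of 100 were as large (10121, highest other 10127), which also excludes chance at 0.05 on the same condition of free exchange. For KO against WT with vehicle, an earlier draw of 25 had held a split above 4994 and below the real count. The highest other splits kept 0.667 to 0.833 of the real difference, as the share of libraries left in their own group less that exchanged, averaged over the sexes, whereas splits that kept under 0.1 called at most 33 rows in any of these 7 comparisons. The splits for the 4 responses to treatment exchanged single libraries within a sex without regard to the culture. Among the splits that part as many cultures as the real one (6 in WT and 4 in KO), the real count was again the highest: for Tg+PDBu 14 others reached 4683 in WT and 13 reached 2913 in KO, and for LPS 17 reached 5157 in WT and 13 reached 2167 in KO. These are too few for a share under 0.05. Splits that part fewer cultures reached 4651, 6291, 4220 and 2492 in the same order. For the responses KO minus WT, whole cultures were exchanged between genotypes, and 1 of 40 splits was as large both for Tg+PDBu (1991, next 1) and for LPS (2527, next 67). Exchanging single libraries instead, which turns the genotype difference itself into a difference of responses, gave 2 of 25 as large in each case, with up to 6096 and 6316 calls.

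In sorted cells, 1 of 100 splits was as large for LPS at 24 h in WT (3979, next 737) and in KO (3593, next 2793), and 1 of 100 for KO against WT with vehicle (4, next 1), so chance can be excluded. For KO against WT at 24 h, 3 of 100 were as large, with 3 calls in the real split and 16 in the highest other, but 2 earlier draws of 25 had given 1 and 3, so the draws do not settle whether chance is excluded. At 6 h the 10 possible splits are too few for a share under 0.05: KO against WT had 3 calls, 5 of 10 splits were as large and the highest other had 813, and WT males against vehicle had 1607, 1 of 10, with 16 in the highest other. A count of 0 is met by all 100 splits whatever the data, so splits cannot test the counts of 0 by edgeR: the LPS response KO minus WT (530 rows at an unadjusted p under 0.05, 10 calls by DESeq2 and 1 by voom, highest other 6), 6 h minus 24 h (765, 11 and 0, highest other 777), the sex difference with vehicle (714, 11 and 0, highest other 1) and at 24 h (767, 2 and 0, highest other 294), the WT response in males minus females (570, 7 and 0, highest other 190), and in culture the sex difference with vehicle (820, 27 and 6, highest other 3). At 6 h, the 4 other splits that put WT replicate 3 and KO replicate 1 together, the mice with low LPS scores, called 134 to 813 rows, and the 5 that parted them called 0. The 777, 294 and 190 calls in the other comparisons were not traced to particular mice.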
